A study of Homo sapiens with 17 samples.

How the data were processed

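The series holds 17 stranded, polyA-selected RNA-seq libraries of total RNA from 3 established human prostate cancer cell lines. Per the labels, LNCaP and VCaP cells were kept for 48 h in steroid-stripped serum and given 10 nM dihydrotestosterone (DHT) for 0, 6 or 24 h, with 1 library per line and time. LNCaP cells were treated with DMSO or enzalutamide with 2 libraries each, for a time that one label gives as 48 h and another as 24 h. MDA-PCa-2b cells received siRNA for 72 h, with 3 libraries of non-targeting siRNA (siNT), 2 of siRNA against the long noncoding RNA ARLNC1 (siARlnc1) and 2 of siRNA against AR (siAR). The description field of the VCaP libraries names LNCaP; the line was taken from the titles, and VCaP was also recognised by its ERG level, which is given with the other observations.

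Per the submitters' processing notes, reads were aligned to GRCh38 with STAR, whose version is not given. Per the file headers, featureCounts 1.4.6 counted paired fragments per gene in stranded mode, giving unnormalised counts for each library on a gene annotation with 53986 identifiers and on MiTranscriptome, an assembly of long RNAs, with 90969 identifiers. The deposited tables of RPKM (reads scaled by exon length and library total) hold the same libraries. Of 2464235 RPKM values, 22 were more than 0.00051 away from the deposited count divided by exon length and the library's summed counts. A reference annotation supplied a symbol for 48503 gene identifiers, matched by identifier. ARLNC1 carries the older symbol PRCAT47 in the files and was matched by its identifier. With bedtools 2.31.1, 34525 MiTranscriptome identifiers overlapped the gene annotation on the same strand.

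Depth was the sum of gene counts per library and ranged from 8.32 to 58.9 M. A count of 0 allows up to 3 counts, which corresponds to 0.051 to 0.361 CPM (counts scaled to the library total) depending on the library. Such limits cover counting error only, and the libraries carry no molecular identifiers. The labels do not say whether the replicates are separate cultures, so they may be technical. The flow cell codes in the file headers place the libraries in 6 sequencing runs. Run 1 held the LNCaP DHT libraries and VCaP at 0 and 6 h, and run 2 held only the library labelled VCaP DHT 24 h. Replicate 1 of DMSO and enzalutamide came from run 3 and replicate 2 of both from run 4. Run 5 held siNT replicates 1 and 2 and both siARlnc1 libraries, and run 6 held siNT replicate 3 and both siAR libraries.

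Each comparison used edgeR 4.0.16 in R 4.3.3: TMM normalisation, removal of low counts with filterByExpr, a robust quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment at a false discovery rate (FDR) of 0.05. The standard error (SE) of a log2 change is its absolute value divided by the square root of F, and so includes the spread between libraries. DHT was tested in 6 libraries with line and time in the fit, so that the lines act as replicates. A further fit tested whether the response to DHT, with 6 and 24 h pooled, differed between the lines. Enzalutamide was tested in 4 libraries and the knockdowns in 7. These comparisons, the gene lists, the rule for naming genes and the first set of alternatives were made before the data were examined. After the runs had been seen, every enzalutamide and knockdown result was also computed with sequencing run in the fit, so that each treated library is set against controls of its own run. For enzalutamide this is the replicate block of the first set of alternatives. That set also held fits with only siNT replicate 3, or only siNT replicates 1 and 2, as the control. With the siNT libraries of its own run as control, each knockdown has the same model there as with run in the fit. Equal counts for siAR and siARlnc1, and equal shared genes, were therefore certain and are no separate check. The pairing of libraries by replicate number was checked by correlating deviations from group means across genes. The correlation was 0.83 for DMSO and enzalutamide, whose replicate numbers are runs, and lay between -0.13 and 0.11 in MDA-PCa-2b, so the replicate block was informative for enzalutamide (2547 genes called, against 0 without it) and the block for MDA-PCa-2b appears only among the alternatives.

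The genes named in each comparison were AR, ARLNC1, KLK3, TMPRSS2, FKBP5 and NKX3-1. To these were added up to 10 genes in each direction with the largest log2 change among those past FDR 0.05, with a mean of at least 1 TMM-normalised CPM and the same direction in every treated against every control library, or the 5 with the smallest p where fewer than 3 passed. List members with the smallest p complete the set. In LNCaP alone, where DHT has no replicate, the rule was added after the data were seen: the 10 largest rises and falls at 24 h with a mean of at least 10 TMM-normalised CPM and the same direction at 6 h. Fold changes against a group at 0 to 3 counts are not printed. There are 27 lists: androgen-induced, androgen-repressed, DNA replication, mitosis, cholesterol synthesis, fatty acid synthesis, polyamine metabolism, unfolded protein response, amino acid response, glycolysis, p53 targets, interferon response, luminal prostate, AR cofactors, basal epithelium, neuroendocrine, steroid metabolism, glucocorticoid-induced, immediate early, mesenchymal, fibroblast, leukocyte, endothelial, mitochondrially encoded, ribosomal protein, prostate lncRNA and ETS factors. They were tested where at least 3 members were measured. Of the members, 1 (PRNCR1 of the prostate lncRNA list) was not in the files. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with an estimated correlation. The latter test has only the residual degrees of freedom, 1 to 4 here, and could hardly pass after adjustment over lists. Failing it does not decide whether a list moved. For genes raised by DHT in LNCaP, camera for enzalutamide with run in the fit gave p = 1.21e-67 at the preset correlation. An estimated correlation of 0.0136 gave p = 0.0415. For single DHT libraries, the log2 change was taken on TMM-normalised CPM plus 0.5. A list's median was placed among those of 10000 random lists matched on expression in 20 bins. The percentile takes no account of correlation between genes of a list or of the spread between libraries.

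The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no low-count filter, a fold of at least 2, limma on log2 (RPKM + 0.1), leaving out each library in turn, a single fit over all 17 libraries, the replicate block, other choices of siNT libraries, and fry for gene sets. Alternatives added after seeing the data were the sequencing run as a covariate in MDA-PCa-2b, the sum of siNT replicates 1 and 2, each DHT line alone with the spread of the other groups, and gene sets defined by fold in LNCaP. Where a left-out library leaves an arm with 1 library, that library is assumed to vary like the others. The overlap of the knockdowns was compared with 20 simulations of unchanged groups that share the controls. Length and GC content were removed with splines of 4 degrees of freedom. Data were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

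The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold in each design. Of the 4-fold changes, it recovered 23% for DHT at 24 h, 20% at 6 h, 13% between these times and 0% for the difference between lines. It recovered 77% for enzalutamide, 60% for siAR, 61% for siARlnc1 and 53% between the knockdowns. With sequencing run in the fit, the shares were 100%, 84%, 91% and 55%. Of the 2-fold changes, it recovered 0% for DHT, 15% for enzalutamide and 2% to 3% for the knockdowns, and 93%, 23%, 43% and 0% with run in the fit. False calls exceeded the nominal rate in several designs: 17 of 40 calls for DHT at 24 h, 11 of 31 at 6 h, 5 of 18 between these times, 15 of 107 for enzalutamide, 4 of 68 for siARlnc1, and with run in the fit 49 of 242 for enzalutamide, 14 of 121 for siAR, 19 of 153 for siARlnc1 and 18 of 73 between the knockdowns. No library was left out of the comparisons. No group held 4 or more libraries and no comparison had 3 libraries on each side, so single outlying libraries were not tested for and libraries were not regrouped.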

Results

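RNA was sequenced from 3 prostate cancer cell lines in which androgen receptor (AR) signalling was raised, blocked or reduced. LNCaP is a line from a lymph node metastasis with a mutated AR, VCaP a line from a vertebral metastasis with amplified AR and a TMPRSS2-ERG fusion, and MDA-PCa-2b a line from a bone metastasis. Of the 17 libraries, 6 form a time course of dihydrotestosterone (DHT), the potent androgen, with 1 library per line and time. Another 4 compare enzalutamide, an AR antagonist, with its solvent DMSO in LNCaP, and 7 compare knockdown of AR or of the AR-associated long noncoding RNA ARLNC1 with a non-targeting control (siNT) in MDA-PCa-2b. Summed gene counts in LNCaP at 0, 6 and 24 h of DHT were 54.8, 51.1 and 56.9 M. In VCaP they were 46.5, 54.4 and 55.8 M. The DMSO libraries held 41.1 and 43.1 M and the enzalutamide libraries 41.9 and 52.4 M. The siNT libraries held 8.32, 58.9 and 44.6 M, the siARlnc1 libraries 49.9 and 57.0 M and the siAR libraries 49.2 and 43.0 M. Between 20060 and 25883 genes were detected per library. Mitochondrially encoded transcripts took 7.67% to 11.9% of the counts in the DHT libraries, 2.09% to 3.83% in the DMSO and enzalutamide libraries and 2.45% to 4.62% in MDA-PCa-2b.

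On GRCh38, the genes followed throughout are AR (chromosome X, 67544032 to 67730619), ARLNC1 (chromosome 16, 80828735 to 80892595, a lincRNA) and 4 protein-coding genes long known as androgen-induced. These are KLK3, which encodes prostate-specific antigen (chromosome 19, 50854915 to 50860764), the membrane protease gene TMPRSS2 (chromosome 21, 41464551 to 41508159), FKBP5, which encodes a steroid receptor co-chaperone (chromosome 6, 35573585 to 35728583), and NKX3-1, a prostate homeobox gene (chromosome 8, 23678693 to 23682927). Unless stated otherwise, levels are CPM, that is counts scaled to the library's own total without TMM factors. Changes are on the log2 scale and come from TMM-normalised values, so they can differ from the ratio of the levels printed beside them. For single DHT libraries, folds and log2 changes compare TMM-normalised CPM plus 0.5. The added 0.5 makes folds smaller for genes with few counts at 0 h, such as ARLNC1, STEAP4, HPGD and UGT2B28 in LNCaP.

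The DHT series asks which genes respond to androgen after steroid withdrawal. In LNCaP the androgen-induced genes were higher at 6 h and higher still at 24 h. FKBP5 was 6.77-fold higher at 6 h and 32.0-fold higher at 24 h than at 0 h. KLK3 was 5.21-fold and 19.9-fold higher, TMPRSS2 5.15-fold and 11.6-fold, and NKX3-1 5.16-fold and 8.32-fold. ARLNC1 stood at 0.221, 0.613 and 3.24 TMM-normalised CPM at 0, 6 and 24 h, which with 0.5 added is 1.54-fold and 5.19-fold higher, while AR itself was lower, with log2 changes of -0.27 and -0.55. There is 1 library per line and time and therefore no replicate check on any of these values.

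Among the largest upward differences in LNCaP at 24 h were the metalloreductase gene STEAP4 (298-fold), the kinase scaffold gene AKAP12 (64.0-fold), HPGD, which encodes a prostaglandin-degrading enzyme (63.3-fold), the kallikrein gene KLK2 (52.9-fold), the nicotinic receptor gene CHRNA2 (46.2-fold) and the kinase gene SGK1 (43.6-fold). These genes differed in pace. SGK1 was already 27.0-fold higher at 6 h and HPGD 6.86-fold, whereas AKAP12 was 1.74-fold and UGT2B28, which encodes a steroid-glucuronidating enzyme, was 1.75-fold higher at 6 h and 41.3-fold at 24 h. Among the largest downward differences at 24 h were those of the opioid receptor gene OPRK1 (-4.67), the sucrase-isomaltase gene SI (-4.40), CAMK2N1, which encodes a CaM kinase inhibitor (-4.05), the chemokine receptor gene ACKR3 (-3.48) and the dopa decarboxylase gene DDC (-3.24). Of 9474 genes with a mean of at least 10 TMM-normalised CPM in LNCaP, 148 were at least 2-fold higher and 24 at least 2-fold lower at 6 h. At 24 h these counts were 511 and 277, of which 496 and 260 lay on the same side at 6 h.

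**Figure D1:**
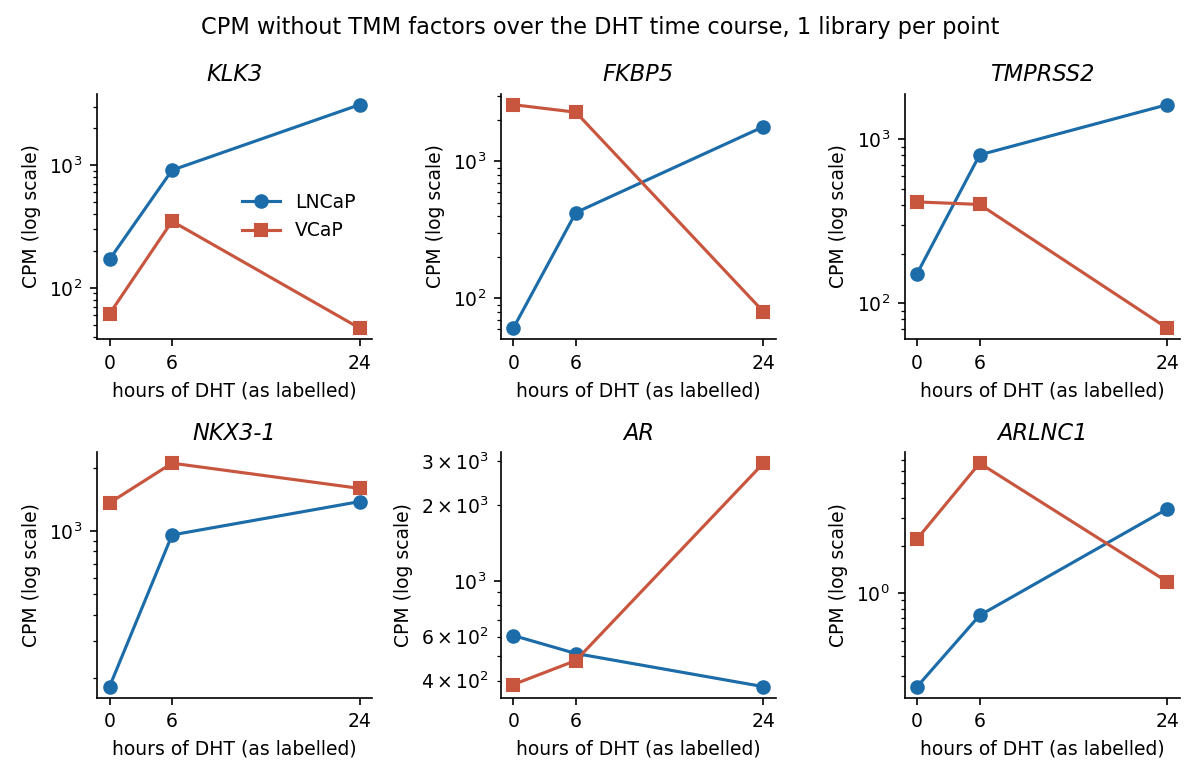
Counts in CPM without TMM factors (log axis) of KLK3, FKBP5, TMPRSS2, NKX3-1, AR and ARLNC1 against labelled hours of DHT in LNCaP (circles) and VCaP (squares), with 1 library per point and no error bars because there are no replicates. FKBP5 went from 60.5 to 1789 CPM in LNCaP and from 2590 to 79.8 CPM in VCaP between the libraries labelled 0 and 24 h.

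The gene lists in LNCaP moved with these genes. The median change of the 37 androgen-induced genes was 1.67 at 6 h and 3.25 at 24 h, each at percentile 100 among random lists matched on expression. That of the androgen-repressed genes was -0.27 (percentile 0.15) and -1.99 (percentile 0). At 24 h the medians of the lipid lists were high, at 1.41 for cholesterol synthesis and 1.07 for fatty acid synthesis, both at percentile 100, against 0.28 and 0.08 at 6 h. The unfolded protein response stood at 1.14 (percentile 100), glycolysis at 0.78 (percentile 99.96), polyamine metabolism at 0.51 (percentile 99.3) and the amino acid response at 0.41 (percentile 99.5). Glucocorticoid-induced genes, which share many binding sites with AR, had medians of 2.02 and 2.15 at 6 and 24 h. DNA replication (-0.05, percentile 10.7) and mitosis (-0.22, percentile 0.12) were near or below 0 at 24 h. So were ribosomal protein (-0.18, percentile 0) and mitochondrially encoded genes (-0.33, percentile 0.02). Without replicates, the percentiles cannot tell small shifts from differences between libraries.

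VCaP gave another picture, above all in the library labelled VCaP DHT 24 h, which is alone in its sequencing run. In the library labelled 6 h KLK3 was higher by 2.45 and ARLNC1 by 1.39, while TMPRSS2 (-0.10) and FKBP5 (-0.23) were close to their labelled 0 h level. FKBP5 was already at 2590 CPM in the VCaP library labelled 0 h, against 1789 CPM in LNCaP at 24 h of DHT. The order of all 3 VCaP labels is in doubt, as taken up with the results for a closer look. All VCaP changes, those at 6 h included, and the fits of both lines carry that doubt. In the library labelled VCaP DHT 24 h, FKBP5 was lower than at 0 h by a log2 change of -5.34, TMPRSS2 of -2.87, ARLNC1 of -0.96 and KLK3 of -0.71, and AR was higher by 2.61, at 2898 against 476 TMM-normalised CPM. STEAP4 (-5.43), SGK1 (-5.68) and TIPARP, which encodes an ADP-ribosyltransferase (-5.68), were also low there. The transcription factor gene ERG, which the TMPRSS2 fusion places under androgen control in this line, was at 0.81 at 6 h and -1.16 in that library. These genes outside the key set were chosen after their values were seen. Of 9546 genes with a mean of at least 10 TMM-normalised CPM in VCaP, 712 were at least 2-fold higher and 741 at least 2-fold lower at 6 h, and 569 and 1032 in the library labelled VCaP DHT 24 h.

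By list, the androgen-induced genes had a median of 0.58 (percentile 100) in VCaP at 6 h and of -1.26 (percentile 0) in the library labelled VCaP DHT 24 h, where 33 of 37 were lower. All 11 androgen-repressed genes were higher there, with a median of 1.27. At 6 h cholesterol synthesis (1.45) and fatty acid synthesis (1.13) stood at percentile 100, and the DNA replication genes were all lower (30 of 30, median -2.05, percentile 0), as were the 41 ribosomal protein genes (median -0.83, percentile 0). The interferon list was at 0.70 (percentile 100) and the amino acid response at -0.89 (percentile 0.01). In the library labelled VCaP DHT 24 h, cholesterol synthesis was at -0.47 (percentile 6.72), fatty acid synthesis at -0.45 (percentile 17.2), glucocorticoid-induced genes at -2.41 (percentile 0), the unfolded protein response at -1.19 (percentile 0) and p53 targets at 0.44 (percentile 99.4).

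**Figure D2:**
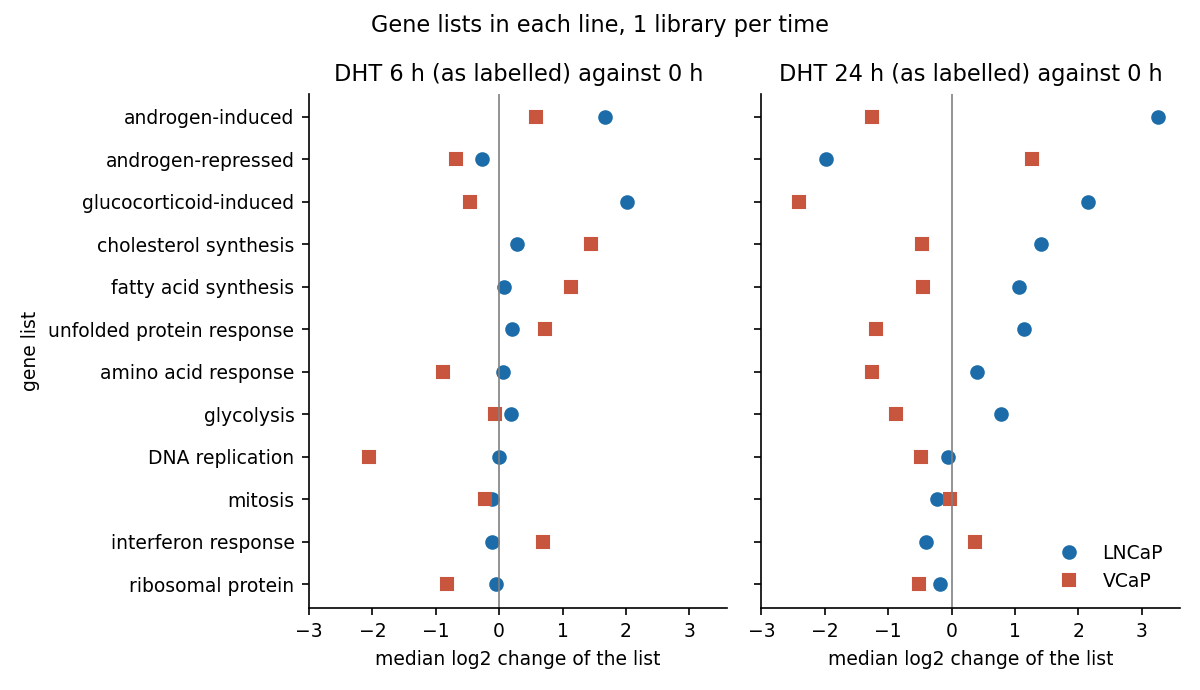
Median log2 change of 12 gene lists against 0 h in LNCaP (circles) and VCaP (squares) at labelled times of 6 h (left) and 24 h (right), 1 library per time and no error bars. The androgen-induced median is 3.25 in LNCaP and -1.26 in the library labelled VCaP DHT 24 h.

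Across 19619 genes, the changes of the lines correlated at Pearson r = -0.12 at 6 h and -0.38 at 24 h (Spearman -0.12 and -0.33). LNCaP at 24 h against VCaP at 6 h gave 0.069, a setting chosen after seeing the data. Within LNCaP, 6 and 24 h correlated at 0.72, and within VCaP at 0.40, with a shared 0 h library in each case. Genes are not independent replicates, so no p-value is attached.

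With the lines as replicates, KLK3 (2.64, SE 1.49), FKBP5 (1.45, SE 2.88), ARLNC1 (2.08, SE 1.54), NKX3-1 (1.44), TMPRSS2 (0.68) and AR (1.23) had adjusted p-values of 1 at 24 h. ZNF385B, a zinc finger gene (2.48, SE 0.365), and the sodium pump gene ATP1B1 (-2.60, SE 0.542) were among those with the smallest p and did not pass either. edgeR called 0 of 19619 genes at 24 h, with 296 at an unadjusted p under 0.05. DESeq2 called 15 and limma on RPKM 0. Leaving out the library labelled VCaP DHT 24 h gave 33 genes, 27 higher and 6 lower, and leaving out the LNCaP 24 h library gave 10. At 6 h edgeR called 0 (157 at an unadjusted p under 0.05, DESeq2 5, limma 0), with KLK3 at 2.44 (SE 1.25).

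Between 6 and 24 h edgeR called 0 genes (209 at an unadjusted p under 0.05, DESeq2 1, limma 0). The estrogen receptor gene GPER1 (-1.86) and the transcription regulator gene ID3 (-1.56) were among those with the smallest p and did not pass. Leaving out the LNCaP 24 h library gave 51.

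At the preset correlation, 7 lists passed at 24 h: androgen-induced (median 1.28), cholesterol synthesis (0.69), prostate lncRNA (0.63) and leukocyte markers (0.86) upward, and DNA replication (-0.36), the amino acid response (-0.51) and ribosomal protein genes (-0.32) downward. All had an adjusted p = 0.983 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. At 6 h 10 lists passed, among them androgen-induced (0.78), cholesterol synthesis (1.01), fatty acid synthesis (0.74), the unfolded protein response (0.53), interferon (0.39), luminal prostate (0.47) and prostate lncRNA (0.49) upward and DNA replication (-0.90), ribosomal protein (-0.47) and the amino acid response (-0.39) downward. For these the adjusted p = 0.655 with an estimated correlation, except 0.726 for the unfolded protein response. Between 6 and 24 h 5 passed, DNA replication (0.65) and leukocyte (0.89) upward and cholesterol synthesis (-0.35), the unfolded protein response (-0.34) and interferon (-0.31) downward, with an adjusted p = 0.958 with an estimated correlation. At 24 h the median and the test differed in sign for androgen-repressed (0.11, test downward), basal epithelium (-0.25, upward), neuroendocrine (0.01, downward) and glucocorticoid-induced genes (-0.05, upward), and none of these passed. At 6 h p53 targets (-0.04, mean 0.00, upward) differed likewise, as did glucocorticoid-induced (0.08, downward) and endothelial genes (0.65, mean -0.02, downward) between 6 and 24 h, without passing. For glucocorticoid-induced genes at 6 h the median (0.13, test upward) and the mean (-0.54) differed in sign, and the list did not pass.

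Whether the lines respond differently was tested as an interaction. TMPRSS2 (-3.98, SE 1.71), FKBP5 (-5.48, SE 2.90) and NKX3-1 (-2.48, SE 0.731) were relatively lower and AR (2.26) relatively higher in VCaP, with adjusted p-values of 0.996. The smallest p belonged to genes such as SGK1 (-10.91), the retinol dehydrogenase gene RDH10 (-6.43), the Wnt ligand gene WNT7B (-5.55) and RAB27B, a vesicle transport gene (3.85), at an adjusted p of 0.892. edgeR called 0 of 21073 genes (939 at an unadjusted p under 0.05, DESeq2 168, limma 0). In total 10 lists passed at the preset correlation, with adjusted p-values of 0.730 to 0.870 with an estimated correlation, and their medians are given among the results for a closer look. Median and mean differed in sign for fatty acid synthesis (0.05 and -0.40), luminal (0.17 and -0.12), basal (0.21 and -0.55), neuroendocrine (-0.30 and 0.49), steroid metabolism (0.01 and -0.37), mesenchymal (0.44 and -1.20) and prostate lncRNA genes (-0.24 and 0.18), none of which passed.

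The enzalutamide comparison asks which genes depend on AR activity in LNCaP, here with no steroid withdrawal in the labels. Androgen-induced genes fell. With sequencing run in the fit, NKX3-1 fell by 2.93 on the log2 scale (SE 0.106, FDR 9.13e-05, n = 2 per group), KLK3 by 2.39 (SE 0.0957, FDR 9.9e-05), TMPRSS2 by 2.40 (SE 0.104, FDR 0.000131), FKBP5 by 1.84 (SE 0.0969, FDR 0.000208) and ARLNC1 by 2.85 (SE 0.255, FDR 0.001). AR rose 1.32-fold (log2 0.39, SE 0.0796, FDR 0.0186). Levels differed between the runs within each group: KLK3 was 3348 ± 2000 CPM (SD, n = 2) in DMSO and 619 ± 288 CPM in enzalutamide, NKX3-1 882 ± 355 and 121 ± 67.5, and ARLNC1 4.96 ± 4.35 and 0.650 ± 0.433.

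**Figure D3:**
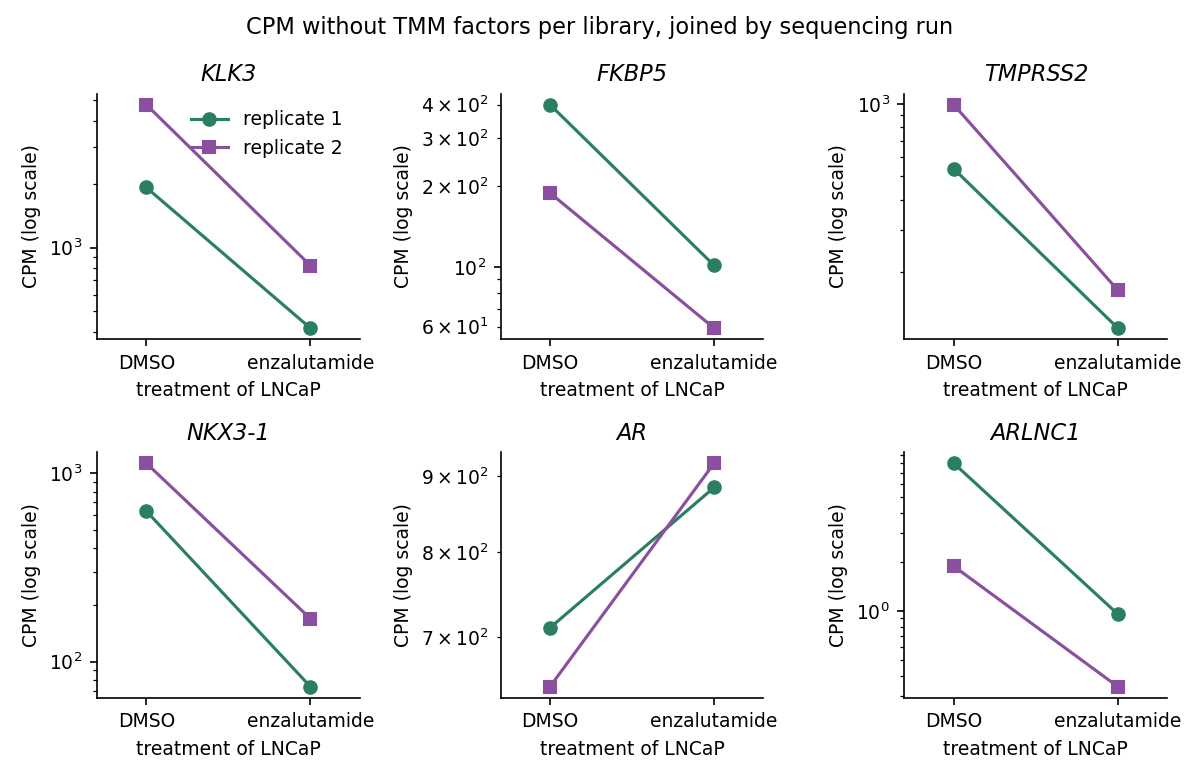
Counts in CPM without TMM factors (log axis) of the key genes in LNCaP with DMSO or enzalutamide, each point a library and each line joining the replicates that share a sequencing run. KLK3, FKBP5, TMPRSS2, NKX3-1 and ARLNC1 are lower with enzalutamide in both runs and AR is higher in both.

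Among the named genes, the ion channel gene TRPM8 fell by 5.13 (SE 0.17), CHRNA2 by 5.36 (SE 0.222) and the sialyltransferase gene ST6GALNAC1 by 4.74 (SE 0.463). The other named genes that fell, CCDC141, SLC38A4, PKP1, DSC1, TTN, KRT14 and ADH1C, had libraries with 0 to 2 counts with enzalutamide, and no fold is given for them. Among the largest rises were the phospholipase D gene PLD1 (3.79, SE 0.232), OPRK1 (3.71, SE 0.197), the glutamate receptor gene GRIK1 (3.22), the protocadherin gene PCDH11X (2.95) and SI (2.65, SE 0.325). OPRK1 and SI were among the genes lowest in LNCaP with DHT, and CHRNA2 among those highest.

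Of the 37 androgen-induced genes, 33 fell and 0 rose (0 higher and 34 lower adjusted over the list alone; median -1.45), including KLK2 (-3.45, SE 0.08), SLC45A3, which encodes prostein (-2.78, SE 0.08), and HPGD (-4.11, SE 0.17). Of the 11 androgen-repressed genes 6 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.90), including OPRK1, ACKR3 (1.42, SE 0.09) and CAMK2N1 (1.72, SE 0.20). These lists passed the set test at the preset correlation, with an adjusted p = 0.653 and 0.796 with an estimated correlation.

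Cell cycle genes also fell: 27 of 30 DNA replication genes (29 adjusted over the list alone; median -0.56), such as the nucleotide reductase gene RRM2 (-0.77) and the helicase gene MCM5 (-0.83), and 18 of 24 mitosis genes (22 adjusted over the list alone; median -0.47), such as the mitotic kinase gene PLK1 (-0.71) and MKI67 (-0.54), with 0 rising in either list. Lipid genes also fell, 11 of 23 for cholesterol synthesis with 1 rising (16 and 1 adjusted over the list alone; median -0.44) and 8 of 17 for fatty acid synthesis with 0 rising (8 adjusted over the list alone; median -0.42). Examples are the sterol reductase gene DHCR24 (-1.08, SE 0.08) and the fatty acid elongase genes ELOVL7 (-2.38, SE 0.15) and ELOVL5 (-1.43). Each of these lists had an adjusted p = 0.796 with an estimated correlation.

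The other lists that passed were glycolysis (4 of 16 fell, 7 adjusted over the list alone; median -0.21; HK2, a hexokinase gene, -0.81), the unfolded protein response (3 of 20 fell, 3 adjusted over the list alone; median -0.16), glucocorticoid-induced genes (4 of 8 fell and 1 rose, 5 and 2 adjusted over the list alone; median -0.64; ZBTB16 -1.81, TSC22D3 0.76) and mesenchymal genes (2 of 6 fell, 4 adjusted over the list alone; median -0.87; SNAI2 -3.17, TWIST1 -1.34). Their adjusted p = 0.796 with an estimated correlation, 0.802 for the unfolded protein response.

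Lists that did not pass held single responders. In steroid metabolism (1 of 17 rose, 4 fell; 3 and 4 adjusted over the list alone) the glucuronidation genes UGT2B15 (2.08) and UGT2B28 (-2.59) moved apart. In the prostate lncRNA list (3 of 16 rose, 5 fell; 4 and 5 adjusted over the list alone) MALAT1 rose by 0.89 and the antisense RNA CTBP1-AS fell by 2.17. In the luminal list (2 of 16 rose, 2 fell; 3 and 3 adjusted over the list alone) FOLH1, which encodes prostate-specific membrane antigen, rose by 0.76; its median was 0.09 and its mean -0.12, with the test downward. Of the p53 targets 2 of 20 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of -0.16 and the test upward, and of the AR cofactors 2 of 14 rose (2 and 1 adjusted over the list alone), NCOA3 by 0.94. Polyamine metabolism had 4 of 12 lower (5 lower and 1 higher adjusted over the list alone).

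The remaining lists with enzalutamide had 0 to 3 members past the threshold in either direction: amino acid response (0 up, 1 down, 0 adjusted over the list alone), interferon (1 and 1, also adjusted over the list alone), basal epithelium (0 and 1; 1 and 2 adjusted over the list alone), immediate early (1 and 1, also adjusted over the list alone), fibroblast (1 and 1; 2 and 2 adjusted over the list alone), neuroendocrine (0), endothelial (0), mitochondrially encoded (3 and 0, also adjusted over the list alone) and ribosomal protein (3 and 0; 0 adjusted over the list alone). Their medians lay between -0.10 and 0.30.

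With run in the fit, edgeR called 2547 of 17156 genes, 1265 higher and 1282 lower, of which 582 changed at least 2-fold. DESeq2 with the same block called 1846. Without the run, as first laid out, edgeR called 0 (1011 at an unadjusted p under 0.05, DESeq2 207, limma 0) at similar changes, KLK3 at -2.45 with an adjusted p of 0.767 and SLC45A3 at -2.78 with 0.189, and leaving out DMSO replicate 1 or DMSO replicate 2 gave 4 each. The block leaves 1 residual degree of freedom, and in simulated data 49 of 242 calls of this design were false.

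The siAR comparison asks which genes depend on AR in MDA-PCa-2b. AR stood at 346, 337 and 180 CPM in the siNT libraries, 227 and 189 CPM with siARlnc1 and 91.7 and 98.6 CPM with siAR. With run in the fit, where siAR is set against the siNT library of its own run, the change of AR was -0.96 (SE 0.183, FDR 0.0439, n = 2 against 1). Against all siNT libraries it was -1.54 (SE 0.299, FDR 0.067). ARLNC1 was at -2.01 within runs (SE 0.161, FDR 0.0121) and at -2.04 against all siNT libraries (SE 0.166, FDR 0.00822). With 1 control library, the fit within runs takes its spread from the siAR pair, the siARlnc1 pair and siNT replicates 1 and 2. The siAR pair had a chi-square of 6.96 per degree of freedom and the siARlnc1 pair 238. The siNT replicates 1 and 2 are near-identical (chi-square of 1.59 per degree of freedom). With these summed, the changes within runs were -0.99 for AR (FDR 0.169) and -2.04 for ARLNC1 (FDR 0.123), neither of which passed.

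**Figure D4:**
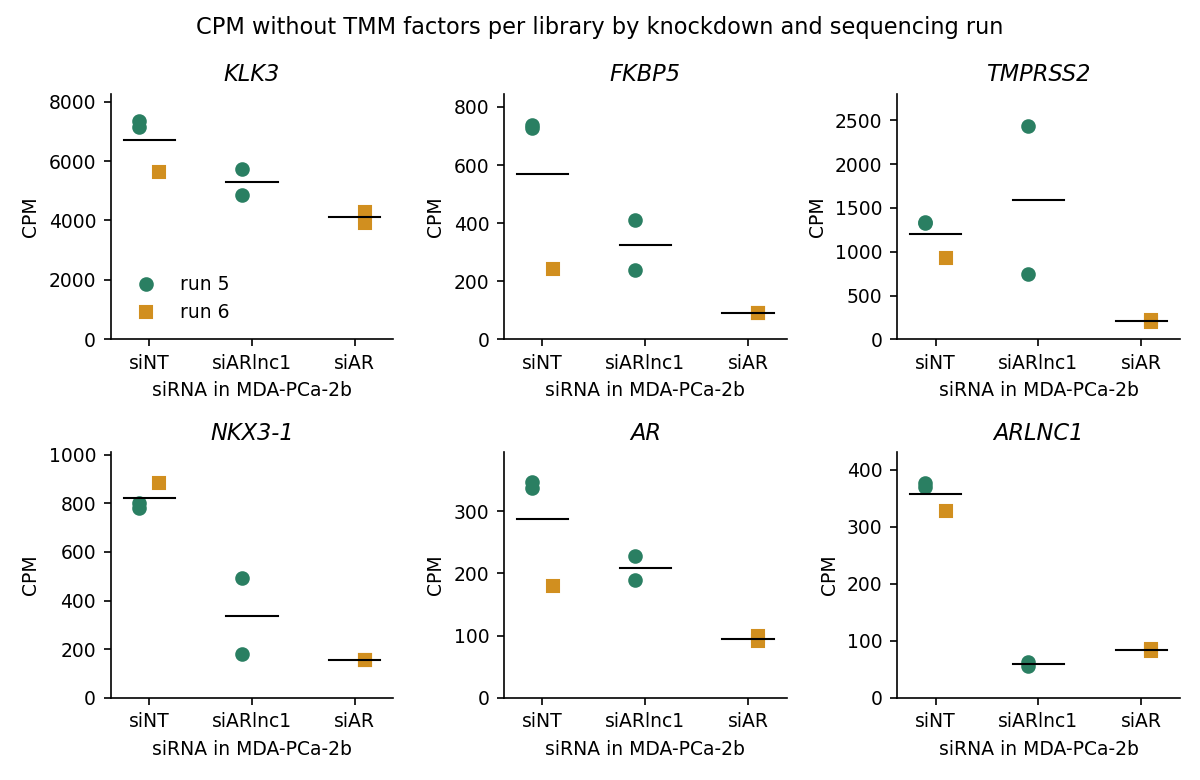
Counts in CPM without TMM factors of the key genes in each MDA-PCa-2b library by siRNA, with circles for run 5, squares for run 6 and a bar at the group mean. AR lies between 91.7 and 98.6 CPM with siAR, and FKBP5 and AR are lower in the siNT library of run 6 than in those of run 5.

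The androgen-induced reporters did not reach the threshold: NKX3-1 was at -2.56 within runs (FDR 0.059) and -2.37 overall (FDR 0.0679), TMPRSS2 at -2.22 (FDR 0.105) and -2.50 (FDR 0.0827), FKBP5 at -1.45 (FDR 0.0705) and -2.58 (FDR 0.0764) and KLK3 at -0.50 (FDR 0.149) and -0.66 (FDR 0.164). KLK3 stood at 4102 ± 266 CPM (SD, n = 2) with siAR against 6706 ± 929 (n = 3) with siNT. Genes that fell in both fits were CHRNA2, by 5.21 within runs (SE 0.214, FDR 0.0063), CTBP1-AS by 4.29, the antiviral ligase gene HERC5 by 4.03 and the myosin-binding gene MYBPC1 by 3.96. Genes that rose in both were REG4, which encodes a secreted lectin (6.85, SE 0.43, FDR 0.00851), the insulin-like growth factor binding protein gene IGFBP3 (4.30, SE 0.758, FDR 0.0382), the homeobox gene SIX2 (4.20) and MGP, which encodes a calcification inhibitor (4.08). No fold is given for PTH, PZP, CFTR, KCNC2 and TEX11, which passed in both fits with libraries at 0 to 3 counts.

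By list within runs, 7 of 36 androgen-induced genes fell and 2 rose (16 and 2 adjusted over the list alone; median -1.17), among them the hormone-responsive gene GREB1 (-1.82, SE 0.11) and MPHOSPH9 (-1.56), with the kinase gene TNK1 higher (1.26). Cholesterol synthesis had 4 of 24 lower and 0 higher (7 adjusted over the list alone; median -0.91), such as the sterol reductase gene DHCR7 (-1.11), and fatty acid synthesis 4 of 16 lower (6 adjusted over the list alone; median -0.42), such as the desaturase gene SCD (-1.66, SE 0.20). Of the mitosis genes 6 of 24 rose and 0 fell (7 adjusted over the list alone; median 0.67), such as the cyclin genes CCNB2 (1.20) and CCNB1 (0.93). Ribosomal protein genes had 2 of 41 lower (10 adjusted over the list alone; median -0.22), and the prostate lncRNA list 3 of 18 lower (4 adjusted over the list alone; median -0.46), with the prostate cancer marker PCA3 at -2.04 (SE 0.33). For these lists the adjusted p = 0.783 with an estimated correlation, 0.645 for prostate lncRNA.

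Without the run, 7 lists passed: androgen-induced (6 of 36 lower, 1 higher; 22 and 1 adjusted over the list alone; median -1.37), cholesterol synthesis (4 of 24 lower; 13 lower and 1 higher adjusted over the list alone; -1.03), fatty acid synthesis (3 of 16 lower; 8 adjusted over the list alone; -1.04), DNA replication (0 of 30; 2 lower adjusted over the list alone; -1.19), the amino acid response (0.73), mitochondrially encoded (0.42) and ribosomal protein genes (0.33). Their adjusted p-values with an estimated correlation lay between 0.733 and 0.752. Part of this moved with the controls: in siNT replicate 3 against replicates 1 and 2 the median of the DNA replication genes was -1.60, of mitosis -1.04, of ribosomal protein 1.07, of the amino acid response 1.04, of fibroblast genes 1.01, of mitochondrially encoded genes 0.68 and of androgen-induced genes -0.36. Within runs the DNA replication median with siAR was 0.02 (1 of 30 lower, 0 adjusted over the list alone).

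Lists that did not pass within runs included AR cofactors (3 of 14 rose; 3 adjusted over the list alone), the unfolded protein response (3 of 20 rose; 3 adjusted over the list alone), polyamine metabolism (1 of 12 rose, 2 fell; the arginase gene ARG2 -3.11, SE 0.20), the luminal list (2 of 16 rose, 1 fell; the racemase gene AMACR -1.07, GATA2 0.77), interferon (1 of 23 rose, 1 fell; 5 and 1 adjusted over the list alone; median 0.72, 0.69 with genes at 0 placed at their bound) and immediate early genes (1 of 14 rose, 1 fell; JUNB 3.19, SE 0.27; median 0.56, 0.69 at the bound). Androgen-repressed genes had a median of 0.73 with 1 of 8 lower. The amino acid response (0 of 16), glycolysis (1 of 16 higher), p53 targets (1 of 20 higher), basal epithelium (1 of 8 higher), neuroendocrine (0 of 6), steroid metabolism (1 of 15 higher; median -0.33, -0.36 at the bound, mean 0.48), glucocorticoid-induced (1 of 8 lower), mesenchymal (0 of 7), fibroblast (1 of 8 lower), leukocyte (0 of 3), endothelial (0 of 6), mitochondrially encoded (0 of 13) and ETS factor genes (0 of 3) complete the lists.

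Within runs edgeR called 1158 of 19240 genes with siAR, 631 higher and 527 lower, and against all siNT libraries 252 of 18162, 117 higher and 135 lower, of which 235 were shared. The overall count fell to 0 without siNT replicate 1 and to 1 without siNT replicate 2. It also fell without siAR replicate 1 or siAR replicate 2. Without siNT replicate 3 it came to 6272, with siAR of run 6 set only against siNT of run 5. Within runs it was 0 without siNT replicate 1, siNT replicate 2, siAR replicate 1 or siAR replicate 2, and 9581 or 9613 without siARlnc1 replicate 1 or 2. Summing siNT replicates 1 and 2, which correlate at 0.995 with a chi-square of 1.59 per degree of freedom, gave 0 in both fits.

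The siARlnc1 comparison asks what depends on ARLNC1. ARLNC1 stood at 369, 376 and 329 CPM with siNT and at 63.3 and 55.3 CPM with siARlnc1. It fell by 2.69 within runs (SE 0.145, FDR 0.0299, n = 2 against 2) and by 2.66 against all siNT libraries (SE 0.172, FDR 0.0267). AR was at -0.75 within runs (SE 0.155, FDR 0.0781) and -0.52 overall (FDR 0.448) and did not pass in either fit. The reporters did not pass either: FKBP5 was at -1.20 (FDR 0.105) within runs, NKX3-1 at -1.24 (FDR 0.228), KLK3 at -0.49 (FDR 0.142) and TMPRSS2 at 0.26 (FDR 0.84). The siARlnc1 replicates disagreed on them. Against the siNT of their run TMPRSS2 was at 0.91 in replicate 1 and -0.96 in replicate 2. NKX3-1 was at -0.65 and -2.26, and the androgen-induced list at medians of 0.06 and -1.03. The disagreement was not limited to these genes. Over 19240 genes the changes of the siARlnc1 replicates correlated at 0.36, against 0.96 for the siAR pair. The chi-square per degree of freedom was 238 for the siARlnc1 pair and 6.96 for the siAR pair.

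Genes that rose within runs were the immune checkpoint gene VTCN1 (4.12, SE 0.527, FDR 0.0417), the receptor phosphatase gene PTPRR (4.10, SE 0.522, FDR 0.0417) and SMIM5 (3.02, SE 0.277, FDR 0.0323), each with 3 counts in siNT replicate 1. Others were the cytokine gene TNFSF15 (2.71, SE 0.3, FDR 0.0382), the kinase gene MAPK4 (2.53), MGP (2.27), the flippase gene ATP8B2 (2.25, SE 0.191, FDR 0.0323) and the serine protease gene PRSS22 (2.11, SE 0.125, FDR 0.0299). Genes that fell were the kinase genes PRKG1 (-1.73) and CDK1 (-1.54), the replication gene GINS1 (-1.70), ARMC1 (-1.52, SE 0.0915, FDR 0.0299) and the DNA glycosylase gene NEIL3 (-1.50).

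By list within runs, 4 of 30 DNA replication genes fell and 0 rose (24 adjusted over the list alone; median -0.73), with the clamp loader gene RFC4 (-1.04) beside GINS1, and 3 of 24 mitosis genes fell (4 adjusted over the list alone; median -0.45), with the cytokinesis gene ANLN at -1.16. Of 20 p53 targets 3 rose and 0 fell (10 adjusted over the list alone; median 0.57): the antiproliferative gene BTG2 (1.29, SE 0.14), the apoptosis gene BBC3 (1.76, SE 0.22) and the death receptor gene FAS (1.47, SE 0.19). Their adjusted p with an estimated correlation was 0.711, 0.77 and 0.417. Of 36 androgen-induced genes 4 fell (6 lower and 1 higher adjusted over the list alone; median -0.34), namely the elongation factor gene ELL2, SORD (-0.98), GREB1 (-0.78) and MPHOSPH9 (-1.20), with an adjusted p = 0.871 with an estimated correlation.

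Further lists that passed at the preset correlation within runs were glycolysis (4 of 16 lower adjusted over the list alone; median -0.37), immediate early (3 higher and 1 lower of 14 adjusted over the list alone; 0.65), fibroblast (3 of 8 higher adjusted over the list alone; 0.86, 1.21 with genes at 0 placed at their bound), mitochondrially encoded (-0.20) and prostate lncRNA genes (1 of 18 lower, ARLNC1; 6 adjusted over the list alone; -0.61). Their adjusted p-values with an estimated correlation were 0.77, 0.68, 0.869, 0.915 and 0.451. Without the run 7 lists passed, p53 targets (7 higher adjusted over the list alone; 0.56), immediate early (0.71) and endothelial (2 of 4 higher adjusted over the list alone; 1.88) upward, and androgen-induced (4 lower adjusted over the list alone; -0.22), mitochondrially encoded (-0.44), ribosomal protein (-0.48) and prostate lncRNA (-0.77) downward, with adjusted p-values of 0.325 to 0.847 with an estimated correlation. Of the other lists within runs, the amino acid response had 1 of 16 higher (CHAC1, 1.70), cholesterol synthesis 1 of 24 higher (TM7SF2, 0.85), fatty acid synthesis 1 of 16 lower (ELOVL7, -1.21) and the rest 0. Within runs the androgen-repressed (0.30, test downward), interferon (0.06, mean -0.38), steroid metabolism (-0.12, mean 0.14), basal (-0.14, -0.26 at the bound, mean 0.11), mesenchymal (0.00, -0.13 at the bound), leukocyte (0.87, 0.58 at the bound) and endothelial (1.64, 1.99 at the bound) lists did not pass. Against all siNT libraries the median and mean of siARlnc1 differed in sign for androgen-repressed (-0.21 and 0.12), steroid metabolism (-0.03 and 0.05), mesenchymal (0.25 and -0.34) and fibroblast genes (0.07 and -0.63), which did not pass either.

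edgeR called 247 of 19240 genes with siARlnc1 within runs, 138 higher and 109 lower, and 1 against all siNT libraries (ARLNC1; 2530 at an unadjusted p under 0.05, DESeq2 915, limma 1). The overall count was 0 without siNT replicate 1 or 2, 284 without siNT replicate 3, and 32 or 4 without siARlnc1 replicate 1 or 2. Within runs it was 0 without siNT replicate 1, siNT replicate 2, siAR replicate 1 or siAR replicate 2 and 9708 or 7847 without siARlnc1 replicate 1 or 2. Summing siNT replicates 1 and 2 gave 0 in both fits.

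Setting siAR against siARlnc1 asks where the knockdowns differ. The siARlnc1 libraries are all in run 5 and the siAR libraries all in run 6. Without the run, this contrast therefore cannot be told apart from run. With run in the fit, called within runs here, each knockdown is first set against siNT of its own run. In run 6 siNT replicate 3 is the only such control. REG4 was higher with siAR by 6.57 within runs (SE 0.476, FDR 0.0202), ATP1B1 by 3.52 (SE 0.162, FDR 0.0194) and the transcription factor gene JUNB by 3.07, and CHRNA2 was lower by -4.83 (SE 0.263, FDR 0.0202), the flippase gene ATP8B2 by -4.21 and the myosin light chain gene MYL9 by -3.71. TMPRSS2 (-2.48, FDR 0.198), ARLNC1 (0.68, FDR 0.178) and AR (-0.21, FDR 0.685) did not pass. Mitosis had 2 of 24 higher with siAR (14 adjusted over the list alone; median 1.15), DNA replication 0 of 30 (12 higher adjusted over the list alone; 0.77), glycolysis 0 of 16 (4 higher adjusted over the list alone; 0.71), cholesterol synthesis 4 of 24 lower (5 adjusted over the list alone; -0.83) and fatty acid synthesis 1 of 16 lower (3 adjusted over the list alone; -0.32). These 5 lists passed at the preset correlation and had an adjusted p = 0.712 with an estimated correlation.

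Within runs edgeR called 153 genes, 68 higher and 85 lower with siAR, and without the run 584, 250 and 334, with 86 shared. Without the run 8 lists passed, androgen-induced (-1.04), DNA replication (-0.87), cholesterol synthesis (-1.55), fatty acid synthesis (-1.12) and glucocorticoid-induced (-1.04) downward and the amino acid response (mean 1.04), mitochondrially encoded (0.87) and ribosomal protein genes (0.83) upward, with an adjusted p = 0.93 with an estimated correlation. DNA replication thus changed sign with the run in the fit. Its median was -1.60 in siNT replicate 3 against siNT replicates 1 and 2, a difference between the runs without any knockdown. Median and mean differed in sign for mesenchymal (-0.12 and 0.59) and fibroblast genes (-0.93 and 1.03) without the run and for basal (1.03 and -0.01) and steroid metabolism genes (-0.25 and 0.34) within runs, and none passed. The overall count was 0 without siAR replicate 1 or 2, and within runs 0 without siNT replicate 1, siNT replicate 2, siAR replicate 1 or siAR replicate 2 and 9080 or 8067 without siARlnc1 replicate 1 or 2.

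Within runs 54 genes were called the same way by both knockdowns, 31 higher (4.53 expected of independent lists) and 23 lower (2.99 expected), while 4 and 13 were called in opposite directions. Shared falls were ARLNC1, GREB1, the phosphodiesterase-related gene PRUNE2 (-1.12 with siAR, -1.12 with siARlnc1), ENDOD1 (-2.58, -1.22) and the sorbitol dehydrogenase gene SORD (-0.86, -0.98). Shared rises were MGP, the Wnt ligand gene WNT5A (1.37, 1.03), the syndecan gene SDC2 (1.84, 1.35) and the protease gene CTSD (1.04, 0.83). ATP8B2 (-1.96, 2.25) and MYL9 (-2.46, 1.24) moved apart; these genes were chosen after their values were seen. The changes correlated at 0.15 across genes (covariance 0.120), against -0.0015 (covariance -0.00055) in 20 simulations of unchanged groups. Within runs the knockdowns have different siNT controls, so a simulated correlation near 0 was set by the design. The simulations shared 0 genes, but unchanged groups should give few calls, so this is no measure for the 54. The overlap rests on siNT replicates 1 and 2 counting as separate libraries: with them summed, or without siNT replicate 1, siNT replicate 2, siAR replicate 1 or siAR replicate 2, 0 genes were called within runs for either knockdown. The simulations took their spread from the fit that counts them separately. Without the run, 1 gene was shared (ARLNC1, 0.0074 expected), and the correlation was -0.10 (covariance -0.093) where shared controls alone gave 0.42 (covariance 0.123). Genes are not independent replicates.

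Genes that respond to agonist, antagonist and knockdown were sought next. The rule laid out first, with calls in all 3 comparisons, gave 0 genes, since DHT gave none, and 2 with DESeq2. With a definition chosen after seeing the data, at least 2-fold in LNCaP at 24 h of DHT and called within runs with enzalutamide and siAR, 49 of 15769 genes were shared. Of these, 39 were higher with DHT and lower in both others (1.23 expected), among them CHRNA2 (5.53 with DHT, -5.36 with enzalutamide, -5.21 with siAR), CTBP1-AS (3.80, -2.17, -4.29), the lysophosphatidic acid receptor gene LPAR3 (2.47, -1.15, -2.87), GREB1 (2.57, -1.28, -1.82) and the zinc-binding glycoprotein gene AZGP1 (2.20, -1.37, -1.03). The other 10 were lower with DHT (0.74 expected), among them ATP1B1 (-1.63, 1.78, 2.99), the ciliary transcription factor gene RFX3 (-3.19, 1.48, 1.34) and ENC1 (-1.92, 0.55, 2.35). The expected counts treat the 3 lists as independent. DHT and enzalutamide, both in LNCaP, alone shared 265 (39.6 expected) and 173 (19.9 expected) in these directions. The expected counts are therefore too low as a measure of what siAR adds. The siAR count behind the shared genes depends on single libraries and was 0 with siNT replicates 1 and 2 summed, as given with that comparison.

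As gene sets, the LNCaP genes at least 2-fold changed at 24 h and changed the same way at 6 h, 496 higher and 260 lower, moved oppositely with enzalutamide. Of the 496, 266 fell and 2 rose with run in the fit (median -0.44), and of the 260, 173 rose and 0 fell (median 0.63), with p = 0.0415 and 0.0358 with an estimated correlation. With fry, the limma rotation test of one-way movement, these values were 0.0232 and 0.0247. Without the run the medians with enzalutamide were -0.44 and 0.64 (camera p = 0.0249 and 0.0498 with an estimated correlation, fry 0.0234 and 0.0637). With siAR within runs 51 of the first set fell and 24 rose (median -0.21, camera p = 0.418 with an estimated correlation, fry 0.195). Of the second 16 rose and 9 fell (median 0.20, camera p = 0.0879 with an estimated correlation, fry 0.0243). Against all siNT libraries the siAR medians were -0.47 (26 fell, 3 rose; camera p = 0.164 with an estimated correlation, fry 0.0492) and 0.35 (8 rose, 1 fell; camera p = 0.0444, fry 0.00691). With siARlnc1 within runs the medians were -0.09 (13 fell, 2 rose; camera p = 0.511 with an estimated correlation, fry 0.363) and 0.24 (3 rose, 1 fell; camera p = 0.0493, fry 0.0204). Against all siNT libraries the siARlnc1 medians were -0.02 (camera p = 0.700 with an estimated correlation, fry 0.739) and 0.05 (camera p = 0.707, fry 0.427), and neither set passed there.

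On MiTranscriptome, the locus G032033 (chromosome 16, 80828651 to 80892718), which overlaps ARLNC1, fell by 2.86 with enzalutamide (SE 0.257, FDR 9.69e-05), by 1.92 with siAR (SE 0.163, FDR 0.00946) and by 2.65 with siARlnc1 (SE 0.147, FDR 0.0177), all with run in the fit. Loci outside the gene annotation also changed. With enzalutamide G052333 (chromosome 21, 41579560 to 41611568) fell by 3.85 (SE 0.238, FDR 1.4e-05) and G003081 (chromosome 1, 84123738 to 84299649) rose by 2.72 (SE 0.129, FDR 2.42e-05). With siAR G004165 (chromosome 1, 119829319 to 119846006) rose by 5.11 (SE 0.301, FDR 0.00373) and G027437 (chromosome 15, 49104154 to 49119844) fell by 4.32 (SE 0.339, FDR 0.00566), against all siNT libraries.

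With run in the fit, edgeR called 2744 MiTranscriptome loci with enzalutamide, 1282 higher and 1462 lower, of which 209 lay outside the gene annotation. It called 992 with siAR, 559 higher and 433 lower, 60 of them outside, and 140 with siARlnc1, 85 higher and 55 lower, 2 of them outside. Both knockdown counts were 0 with siNT replicates 1 and 2 summed and without siNT replicate 1, siNT replicate 2, siAR replicate 1 or siAR replicate 2. Without siARlnc1 replicate 1 or 2 they were 8629 or 8666 with siAR and 8540 or 6673 with siARlnc1. Without the run the counts were 0 (1115 at an unadjusted p under 0.05, DESeq2 234), 326 (167 higher, 159 lower) and 1 (G032033). For DHT at 24 h 0 of 20042 loci were called (334 at an unadjusted p under 0.05, DESeq2 21). Without the run, leaving out Enza replicate 1, Enza replicate 2, DMSO replicate 1 or DMSO replicate 2 gave 16, 2, 6 or 5. The siAR count fell without siAR replicate 1 or 2. It was 26, 33 or 5453 without siNT replicate 1, 2 or 3, the last with siAR set only against siNT of the other run. The siARlnc1 count was 4 or 10 without siARlnc1 replicate 1 or 2 and 0, 0 or 164 without siNT replicate 1, 2 or 3.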

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

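Tests of the times of the VCaP libraries, of foreign RNA in the library labelled VCaP DHT 24 h and of the strength of the ARLNC1 knockdown were chosen only after the result was seen; the tests of length and GC content and of sequencing run were chosen before.

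At the preset correlation, 10 gene lists passed a test of the difference in DHT response between VCaP and LNCaP. None passed with an estimated correlation, a test that has 2 residual degrees of freedom here and could hardly pass after adjustment. The interaction medians (VCaP minus LNCaP) were -2.56 for androgen-induced, 2.26 for androgen-repressed, -1.04 for DNA replication, -0.74 for the unfolded protein response, -1.22 for the amino acid response, -0.74 for glycolysis, 1.42 for interferon, -3.52 for glucocorticoid-induced, -0.81 for immediate early and -0.57 for ribosomal protein genes. With an estimated correlation their adjusted p-values lay between 0.730 and 0.870. Adjusted over the list alone, 1 androgen-induced, 3 amino acid response and 4 glucocorticoid-induced genes were lower, and over all genes 0 were. Of the 6 genes followed throughout, those with opposite directions in the lines at both times were AR (interaction 2.26), TMPRSS2 (-3.98) and FKBP5 (-5.48), each with an edgeR adjusted p of 0.996.

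In the library labelled VCaP DHT 24 h, androgen-induced genes were lower (median -1.26) and AR was higher (2.61) than in the library labelled VCaP DHT 0 h. AR in the library labelled VCaP DHT 24 h lay 1.68 on the log2 scale above the highest of the other 16 libraries. RNA of LNCaP or MDA-PCa-2b cells mixed in therefore cannot account for that AR level. The AR level alone cannot tell whether such RNA was present. ETV1, which both these lines express, was barely measured in any VCaP library, as given under the other observations. This argues against more than traces of such RNA. Interchanged times are a candidate explanation: taking the library labelled 24 h as 0 h, that labelled 0 h as 6 h and that labelled 6 h as 24 h gave a correlation with LNCaP of 0.42 at 24 h, the highest of the 5 other orders, and of 0.36 at 6 h, with androgen-induced medians of 1.26 and 1.71. These values cannot test that explanation, because they restate the pattern itself. Exchanging only the labels 0 and 24 h turns the 24 h correlation of -0.38 into 0.38 by a change of sign. The sequencing run of the library labelled VCaP DHT 24 h cannot be told apart from its treatment, because it shares the run with 0 other libraries. A biological difference between the lines in a late response to DHT stays open: the test of the difference, which called 0 of 21073 genes, pooled 6 and 24 h, and the late response alone was not tested.

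The androgen-induced genes differed between siARlnc1 replicates 1 and 2, with a median of 0.99 in favour of replicate 1. Less knockdown of ARLNC1 in replicate 1 stays open: ARLNC1 was higher there by 0.36, beside 0.045 for the siAR pair, and no value shows how these genes depend on its level. A trend with length or GC content took 2.37% of the variance between the replicates (SD of the trend over genes 0.089) and is too small to be the whole cause, since after its removal the median was 0.92 (quartiles 0.51 and 1.66). Separate cultures or siRNA sequences, which the labels do not describe, may lie behind the difference. No biological explanation was tested.

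DNA replication genes were lower (median -1.60) and ribosomal protein genes higher (1.07) in siNT replicate 3, of run 6, than in siNT replicates 1 and 2, of run 5, with the amino acid response at 1.04, fibroblast genes at 1.01, mitochondrially encoded genes at 0.68 and a mitochondrial share of 4.35% against 2.77% and 2.84%. Length or GC content bias is excluded as the whole cause, because after a correction that took 17.8% of the variance the medians were -1.65 (quartiles -2.05 and -1.23) and 1.09. Sequencing run and culture cannot be told apart: siNT libraries on different runs reached a chi-square of 319 per degree of freedom, and the labels do not say whether any culture was sequenced on both runs. A culture that grew more slowly could give the same pattern and was not tested. Results of the knockdowns against all siNT libraries rest on these controls.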

How the results depend on the processing

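The tests with sequencing run as a covariate in MDA-PCa-2b, with siNT replicates 1 and 2 summed, with LNCaP or VCaP alone, with gene sets by fold in LNCaP and all alternatives of the within-run fits were chosen only after the result was seen, unlike the replicate block and the choices of siNT libraries. Of the named genes' values under the alternatives, 2373 kept their side of the threshold, 749 lost the threshold in the same direction, 219 passed it newly and 6 reversed. A reversal was counted only where either fit passed. The 2373 may therefore include changes of direction among values that passed in neither fit. Of the counts and other main results, 67 stayed within 1.5 times and 78 moved under the alternatives chosen beforehand, and 10 and 63 under those added. RLE size factors in edgeR moved none of the gene counts by that much. Depth limits the low genes: siNT replicate 1 has 8.32 M counts, where a count of 0 allows up to 0.361 CPM. Leaving out a 0 h library could not be fitted for the difference between lines, nor any library for enzalutamide or siNT replicate 3 for the knockdowns within runs. For each value below the cause was not tested, with 2 exceptions. Leaving out libraries or summing them reduces the libraries that inform the spread. Some fits set a knockdown only against libraries of the other run, and their counts cannot be told apart from run. For siAR these are the replicate block, only siNT replicates 1 and 2 as control, and leaving out siNT replicate 3. For siARlnc1 it is only siNT replicate 3 as control. All fits of siAR against siARlnc1 without the run also compare the runs.

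DESeq2 called 15 genes for DHT at 24 h, 5 at 6 h, 1 between the times, 168 for the difference between lines, 207 for enzalutamide, 2290 for siAR, 915 for siARlnc1 and 4157 between the knockdowns, on MiTranscriptome 21 for DHT, 234 for enzalutamide, 1908 for siAR and 611 for siARlnc1, within runs 2426 for siAR, 1704 for siARlnc1 and 1534 between the knockdowns, and gave 2 shared AR-responsive genes. No low-count filter gave 3 genes for enzalutamide, 477 for siAR, 41 for siARlnc1 and 977 between the knockdowns, on MiTranscriptome 8 for DHT, 502 for enzalutamide, 2640 for siAR and 1184 for siARlnc1, and within runs 4042 for enzalutamide, 1813 for siAR, 1056 for siARlnc1 and 879 between the knockdowns. A fold of at least 2 left 582, 684 and 138 within runs for enzalutamide, siAR and siARlnc1, and limma gave 1294 for enzalutamide and 155 for siARlnc1 there.

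A single fit over all 17 libraries gave 1 gene for DHT at 24 h, 79 for siAR and 0 for siARlnc1. The replicate block gave 2547 for enzalutamide, 5265 for siAR, 0 for siARlnc1 and 6567 between the knockdowns, and on MiTranscriptome 2744, 4687 and 0 for the first 3. Sequencing run in the fit gave 1158 for siAR, 247 for siARlnc1, 153 between the knockdowns, 992 and 140 on MiTranscriptome, 54 genes shared by the knockdowns and 5 gene lists between the knockdowns. Only the compared groups in the fit gave 673 for siAR and 0 for siARlnc1. Only siNT replicate 3 as control gave 1158 and 6119, only replicates 1 and 2 gave 6235 and 247, and own-run controls gave 54 shared genes. Summing siNT replicates 1 and 2 gave 0 for siAR and 0 for siARlnc1, and within runs 0 for both, 0 for both on MiTranscriptome and 0 between the knockdowns.

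LNCaP alone gave 1216 genes at 24 h of DHT and 44 at 6 h, and VCaP alone 3367 and 2487, where ARLNC1 (-1.17), TMPRSS2 (-2.82) and FKBP5 (-5.29) reversed against the fit of both lines at 24 h. Gene sets by fold in LNCaP held 756 genes, and the shared AR-responsive genes defined through them were 49. The correlation of LNCaP at 24 h with VCaP at 6 h was 0.069. With an estimated correlation, 0 gene lists passed in each of the 8 comparisons and 0 of the 64 in total. That test had 2 to 4 residual degrees of freedom and could hardly pass, so these counts do not decide whether the lists moved.

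Leaving out each library in turn gave 0 to 33 genes for DHT at 24 h, 0 to 51 between the times, 0 to 4 for enzalutamide, 0 to 6272 for siAR, 0 to 284 for siARlnc1 and 0 to 713 between the knockdowns, on MiTranscriptome 2 to 16 for enzalutamide, 1 to 5453 for siAR and 0 to 164 for siARlnc1, and within runs 0 to 9613 for siAR, 0 to 9708 for siARlnc1, 0 to 9080 between the knockdowns, and on MiTranscriptome 0 to 8666 for siAR and 0 to 8540 for siARlnc1. KLK3 between 6 and 24 h reversed (-3.17 to 1.92), as did TMPRSS2 with siARlnc1 within runs (-0.96 to 0.92) and FKBP5 between the knockdowns within runs (-0.69 to 0.27).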

Other observations

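The genes named here were chosen after their values were seen, and no test was run on them. The lines differ in the ETS transcription factors they express. ERG stood at 410, 743 and 230 CPM in the VCaP libraries labelled 0, 6 and 24 h and at no more than 0.16 CPM in any other library. ETV1 was found in LNCaP (156 to 184 CPM in the DHT libraries, 225 to 370 CPM with DMSO or enzalutamide) and in MDA-PCa-2b (557 to 1730 CPM), and at no more than 0.09 CPM in VCaP. MDA-PCa-2b also held ETV4 (13.7 to 28.0 CPM) and ETV5 (21.1 to 41.9 CPM). Prostate long noncoding RNAs split the lines as well: PCAT14 stood at 517 to 1512 CPM in VCaP and 276 to 1023 CPM in MDA-PCa-2b and at no more than 0.84 CPM in LNCaP, while SCHLAP1 was at 35.0 to 103 CPM in LNCaP and 2.92 to 5.51 CPM in VCaP.

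VCaP carried some neuroendocrine transcripts without any AR inhibitor, but after 48 h in steroid-stripped serum, whose part in this was not tested. Only some of the 12 measured genes of that list are named. The granin genes CHGA (66.1, 20.6 and 98.6 CPM at labelled times of 0, 6 and 24 h) and CHGB (60.5, 34.4 and 83.2 CPM) and the transcription factor gene INSM1 (16.6 to 21.3 CPM) were measured in VCaP, with CHGA at no more than 0.06 CPM in LNCaP. ARLNC1 was far more abundant in MDA-PCa-2b (358 ± 25.7 CPM with siNT, SD, n = 3) than in the LNCaP libraries with DMSO (4.96 ± 4.35, n = 2) or in VCaP (at most 6.70 CPM), and these levels were not tested against each other.

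In the enzalutamide experiment some levels differed between replicates 1 and 2, which are also runs 3 and 4, so run and culture cannot be told apart. The enolase gene ENO2 stood at 9.16 CPM with DMSO and 14.0 with enzalutamide in run 3, and at 160 and 172 CPM in run 4. UGT2B17, which encodes an androgen-glucuronidating enzyme, was at 100 and 126 CPM with DMSO and 187 and 501 CPM with enzalutamide.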
